A study of Mus musculus with 12 samples.

How the data were processed

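Gene expression was measured by RNA sequencing in 12 mouse libraries from C57Bl6 animals, made per the labels with the Ambion miRVANA kit for total RNA and the Illumina TruSeq RNA kit. TAp63 is the set of p63 isoforms that carry the N-terminal transactivation domain, and the TAp63-/- animals lack it. A total of 4 groups were formed from the labels: wild-type (WT) cutaneous squamous cell carcinoma (cSCC, n = 2), TAp63-/- cSCC (n = 4), WT skin (n = 3) and TAp63-/- skin (n = 3). Per the labels, tumours came from mice aged over 35 weeks that had received ultraviolet radiation at 2.5 kJ/m2, 3 times a week, and skin came from mice aged 4 weeks.

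Reads were aligned with TopHat2 2.0 and quantified with Cufflinks 2.0 on the mouse genome build mm10, per the submitters' processing notes. The deposited values are fragments per kilobase of transcript scaled to the library size (FPKM), a unit inferred from Cufflinks and from the values, since the notes do not name it. All 12 columns share 1 distribution: in every library 100% of the sorted values above 0 lay within 1% of the common values. Quantile normalization of the deposited FPKM by the authors was inferred from that, and the step is not recorded in the notes. Read depth per library is therefore unknown, and no counting interval or floor is given. The sum of FPKM ran from 780180 to 780251 per library and says nothing about depth.

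The table holds 37924 entries for 34303 gene symbols. Values of the 272 symbols with more than 1 entry were summed. Of the entries, 36158 Ensembl identifiers were matched to the GENCODE M21 annotation, and 24671 had the same coordinates once the start was counted from 1. Coordinates are given for mm10 with the start counted from 1. Genes with at least 1 FPKM in at least 2 of the 12 libraries were tested (14752 genes).

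Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a variance trend on mean expression and moderated statistics. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, two-sided, and an adjusted p below 0.05 was called changed. Every adjusted p for a gene in the text is limma's. Both genotype comparisons within a tissue were fitted on the 6 libraries of that tissue. Both tumour-skin comparisons and the genotype by tissue interaction were fitted on all 12 libraries. The titles give each library an identifier of its own and the labels do not say what it stands for, so whether each came from a separate animal is not stated and the p-values measure spread between samples.

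A total of 33 gene lists were fixed before the data were examined. They hold 414 entries, of which 410 were present in the table (9 of them found through the Ensembl identifier) and 401 were tested. Each list was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of the comparison. The same test was rerun with the correlation estimated per list, and fry served as a further test of whether a list moved 1 way. List members were counted over all tested genes and, separately, after adjustment over the list alone.

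The genes to be named were set by rule before the data were examined. For each comparison they were the 8 with the largest positive and the 8 with the largest negative change among called genes whose libraries did not overlap between groups and whose higher group averaged at least 5 FPKM, predicted gene models left out. Where none passed, the 4 with the smallest p in each direction were taken. The 3 members with the smallest p of each list that passed were added, together with Trp63, Trp53, Trp73 and 6 genes the study followed up. A gene named outside this rule is said to be so where it appears. Some genes that the rule names are not reported here.

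The procedure was tested on simulated data built from the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold among 14752. The changed genes were drawn from those with a mean of at least 5 FPKM. Recovery of genes with a lower mean was not tested, so the rates below need not hold for them. In the comparison of TAp63-/- with WT skin, 40 of the 2-fold and 79 of the 4-fold changes were recovered. For WT tumours against WT skin it was 15 and 69. For TAp63-/- tumours against TAp63-/- skin it was 34 and 88. For TAp63-/- against WT tumours it was 0 and 25, and for the interaction 11 and 54. Of the calls made at an adjusted p below 0.05, 6 of 125 were false in skin, 18 of 102 for WT tumours against WT skin, 9 of 131 for TAp63-/- tumours against TAp63-/- skin, 0 of 25 between tumours and 14 of 79 for the interaction. In these simulations the share of false calls thus exceeded the nominal rate for both tumour-skin comparisons and for the interaction. That share depends on how many genes change, so it need not hold for the real comparisons.

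Alternatives covered the pseudocount, the filter on low values, rescaling by median-of-ratios or quantiles, the libraries in the fit, limma array weights, a fold threshold, a muscle covariate and each library left out in turn. Covariates for sex and for hair genes, protein-coding genes alone, entries kept per Ensembl identifier and removal of genes listed at 0 beside replicates of 5 or more were added after the data had been seen. A count-based test was not run because the values are not counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.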

Results

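Gene expression was measured in 12 mouse libraries: WT cSCC (n = 2), TAp63-/- cSCC (n = 4), WT skin (n = 3) and TAp63-/- skin (n = 3). Between 13019 and 13073 gene symbols reached 1 FPKM per library, and mitochondrial genes took 26.27% to 33.25% of the summed FPKM. Of the mitochondrial genes, mt-Co1, mt-Atp8, mt-Co3 and mt-Atp6, named after their values were seen, were listed at 0 in WT cSCC replicate 2, WT skin replicate 3 and TAp63-/- skin replicate 1, and the last 3 of these also in TAp63-/- cSCC replicate 1. Those libraries had the lowest mitochondrial shares (26.27%, 27.67%, 27.86% and 28.62%), so the low end of the range goes with genes listed at 0. A total of 367 symbols were listed at 0 in 1 library and at 5 FPKM or more in another of its group, so a listed 0 does not show absence. The read depth was unknown. Across genes, Pearson's r of log2(FPKM + 1) was 0.8643 between both WT tumours, 0.8681 to 0.9166 among TAp63-/- tumours, 0.9293 to 0.9693 among WT skin and 0.9159 to 0.9611 among TAp63-/- skin libraries; genes are not independent replicates. WT cSCC replicate 2 correlated with the skin libraries at 0.7895 to 0.8812, and the other 5 tumours at 0.7183 to 0.8301. Xist and 4 Y-linked genes, taken outside the rule for named genes to read the sex, gave all 6 skin libraries and TAp63-/- cSCC replicate 1 as male and the other 5 tumours as female. Tissue was thus joined to age, ultraviolet exposure and, apart from 1 library, sex, and changes between tumour and skin include all of these. It was also joined to the naming series in the titles, LM for tumours and Su for skin, whose meaning is not stated.

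Trp63 (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102), the targeted gene, encodes the transcription factor p63, which maintains the basal layer of stratified epithelia. Its value was 141 and 97.3 FPKM in the WT tumours and 245, 109, 164 and 258 in the TAp63-/- tumours. WT skin had 113, 100.4 and 119 FPKM, and TAp63-/- skin had 111, 98.2 and 84.5. Trp63 did not differ between the genotypes in skin (log2 change -0.18, SE 0.14, adjusted p = 0.923) or in tumours (0.64, SE 0.41, adjusted p = 1). The value per gene sums the TA and the ΔN isoforms, so it does not check the loss of TAp63.

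**Figure D1:**
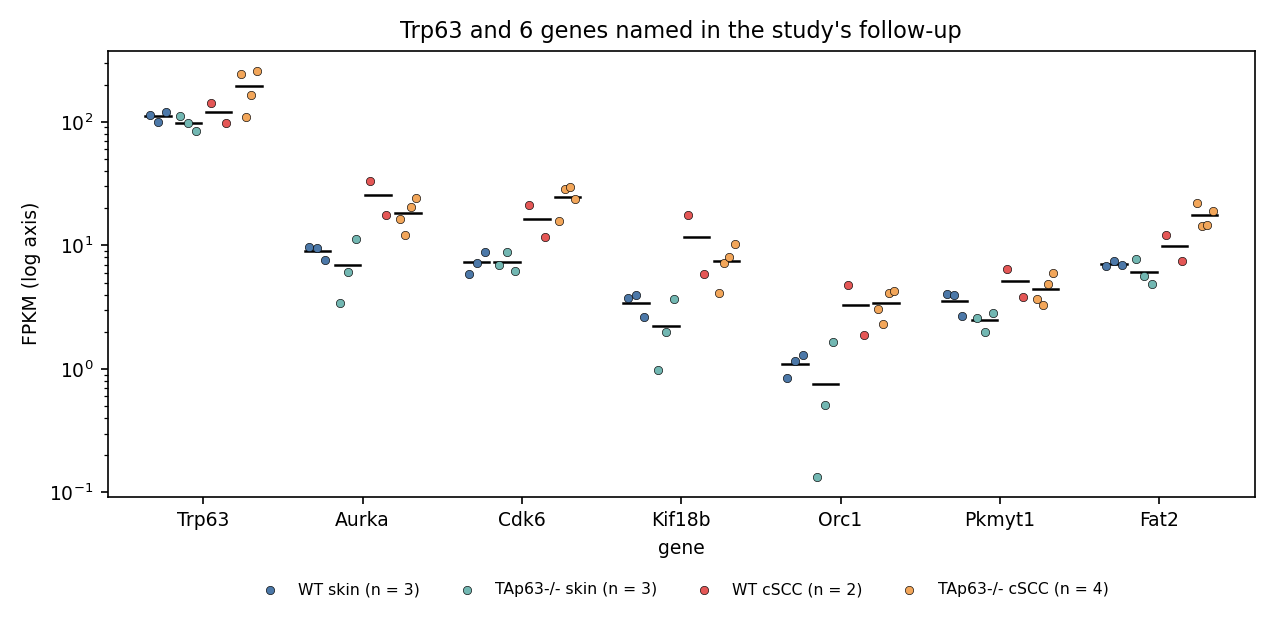
FPKM (log axis) of Trp63 and of the 6 genes the study followed up, in each of the 12 libraries (points) with the group means (bars). Trp63 lay between 84.5 and 258 FPKM in all libraries, and the mean of the TAp63-/- tumours was 194 against 119 in the WT tumours.

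The first comparison asked what loss of TAp63 changed in skin before tumours arose. Skint genes, which encode immunoglobulin-like membrane proteins of keratinocytes and thymic epithelium that shape skin γδ T cells, made up every call. Skint3, Skint4 and Skint9 rose in TAp63-/- skin, while no gene fell.

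With limma, 3 of 14752 genes were called and 738 had an unadjusted p below 0.05. Skint9 (ENSMUSG00000049972, chromosome 4, 112385969 to 112433985) averaged 76.1 ± 24 FPKM (SD, n = 3) in TAp63-/- skin and 0.0369 at most in WT skin (log2 change 6.19, SE 0.24, adjusted p = 0.00171). Skint3 (ENSMUSG00000070868, chromosome 4, 112232245 to 112300468) averaged 45.3 ± 15.4 and at most 0.0186 (5.46, SE 0.27, adjusted p = 0.00494). Skint4 (ENSMUSG00000055960, chromosome 4, 112072016 to 112168076) averaged 19.1 ± 3.09 and at most 0.0209 (4.30, SE 0.15, adjusted p = 0.00171). All 3 genes were also expressed in the WT tumours, at 3.80 ± 0.542, 11.3 ± 5.29 and 2.62 ± 0.301 FPKM. They lie next to each other between Skint1 and Skint2, both named after their values were seen. Skint1 had 9.91 to 14.3 FPKM in WT and 20.2 to 30.1 in TAp63-/- skin, and Skint2 had 25.1 to 43.6 and 11.7 to 16.8. Without WT skin replicates 1, 2 or 3 the count was 5, 8 and 6, and Skint3, TAp63-/- skin vs WT skin, lost its call with a muscle covariate (adjusted p = 0.0571).

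**Figure D2:**
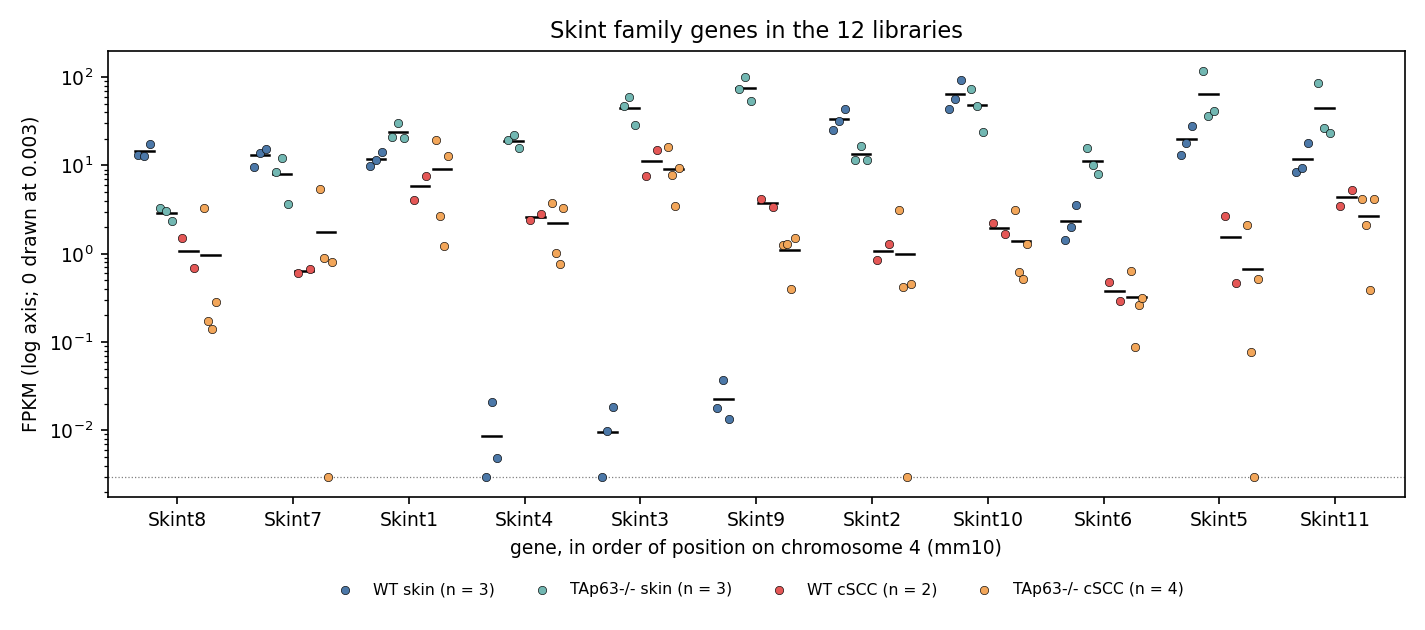
FPKM (log axis, 0 drawn at 0.003) of 11 Skint genes in order of position on chromosome 4, per library (points) with group means (bars). In WT skin Skint3, Skint4 and Skint9 stayed at 0.0369 or less, while TAp63-/- skin averaged 45.3, 19.1 and 76.1.

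Among the lists, camera at the preset correlation placed 3 higher and 6 lower in TAp63-/- skin; none held with an estimated correlation (adjusted p = 0.775 for all 9), and fry called none (lowest adjusted p = 0.663). The immediate-early list, genes that answer to growth and stress signals, was lower by a median of -0.813 (adjusted p = 3.4e-07, and 0.775 with an estimated correlation). Of its 11 genes, 0 passed over all genes and 8 fell when adjusted over the list alone; its median stayed between -0.966 and -0.686 with any 1 library left out. Fosb (-1.80), Junb (-0.81) and Jun (-0.47) had the smallest p of that list, each at an adjusted p of 0.923 over all genes. No member of the other 8 lists passed, either over all genes or adjusted over the list alone.

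The higher lists were fibroblast genes (9 of 9 higher, median 0.461, adjusted p = 0.00121, and 0.775 with an estimated correlation), with Lum at 0.89, Col3a1 at 0.86 and Col1a1 at 0.74, and cornified differentiation genes (20 of 22, median 0.384, adjusted p = 0.00145, and 0.775 with an estimated correlation), with Hrnr at 0.98. Muscle genes were higher in 12 of 16 (median 0.299, adjusted p = 0.0291, and 0.775 with an estimated correlation), with a median of 0.0758 without TAp63-/- skin replicate 1. Hair shaft and sheath genes were lower in 19 of 19 (median -1.54, adjusted p = 0.00121, and 0.775 with an estimated correlation). Lists of adipocyte (median -0.661), melanocyte (-0.618), mitosis (-0.227) and followed-up genes (-0.359) were lower as well, at adjusted p = 0.0144, 0.0196, 0.00664 and 0.0291, and at 0.775 with an estimated correlation. Beside these lists for genes changed, TAp63-/- skin vs WT skin, leaving out TAp63-/- skin replicate 1 gave medians of -0.0307 (hair), -1.44 (adipocyte), -0.02 (melanocyte), 0.101 (mitosis) and -0.16 (followed-up genes), and leaving out TAp63-/- skin replicate 3 gave -2.64, -0.312, -1.14, -0.60 and -0.566. The adipocyte median was -0.199 without TAp63-/- skin replicate 2, and without WT skin replicate 3 the hair and mitosis medians were -2.88 and -0.393. Without WT skin replicate 1 the hair, cornified and fibroblast medians were -0.554, 0.20 and 0.286, and the fibroblast median was 0.707 without TAp63-/- skin replicate 3.

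The next comparison set WT tumours against WT skin. Keratins and envelope proteins of injured epidermis, Krt6a, Krt6b, Krt16, Sprr1b and Sprr2d, rose in the tumours, as they do in wound edges. Inflammatory signals (Cxcl5, Il1a, Il24) and proteases that degrade matrix (Mmp10, Mmp13) rose, and so did Slc2a1, which takes up glucose. Sarcomere genes such as Myl1 and Neb fell, as did Krt77 and Krt15 of the resting epidermis and hair follicle, Adipoq of fat and Dcn of dermal fibroblasts. The mean log2(FPKM + 1) of the muscle list was 8.81 to 9.61 over the skin and 2.32 to 5.75 over the tumour libraries. These values do not tell a change within cells from a different share of tissues or cell types in the piece, for rises or for falls.

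A total of 1687 genes were called, 688 higher and 999 lower in the tumours, and 1387 of them changed at least 2-fold. In simulated data for this comparison 18 of 102 calls were false, but far fewer genes were changed there, so that share need not hold here. Krt6b (ENSMUSG00000023041, chromosome 15, 101676034 to 101680289) averaged 6568 ± 6504 FPKM in the WT tumours (SD, n = 2) and 11.7 ± 9.77 in WT skin (n = 3; log2 change 8.85, SE 0.84, adjusted p = 0.00029). Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) averaged 2289 ± 1703 and 15.7 ± 10.5 (7.06, SE 0.69, adjusted p = 0.000309). Among 14 wound keratinocyte genes 10 rose (11 adjusted over the list alone), 0 fell and 4 did not pass; Sprr1b rose by 7.65, Sprr2d by 7.06 and Krt6a by 5.32 on the log2 scale. The list's adjusted p was 3.45e-09, and adjusted p = 0.255 with an estimated correlation. In this comparison camera with an estimated correlation called 0 of the 33 lists and fry called 7. Fry's adjusted p was 0.00338 for wound and for muscle genes and 0.00314 for chemokine and for Schwann cell genes. Outside the wound list Sprr2i rose by 8.08 and Stfa2, a cysteine protease inhibitor of myeloid cells, by 6.65. SNORA18, a small nucleolar RNA, had 180 and 72.9 FPKM in the WT tumours and was listed at 0 in all 6 skin libraries. It was also listed at 0 in TAp63-/- cSCC replicate 3, and a listed 0 does not show absence.

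Of 19 chemokine and cytokine genes, 6 rose (12 adjusted over the list alone), 0 fell and 13 did not pass (adjusted p = 3.63e-07, and adjusted p = 0.255 with an estimated correlation). Il1a went from 2.03 ± 0.396 to 22.7 ± 7.45 FPKM (2.94, adjusted p = 0.00044), Il24 rose by 4.12 and Cxcl5 by 2.50. Cxcr2, a neutrophil receptor that binds Cxcl5, rose by 2.33, and was the 1 of 9 neutrophil genes that rose (1 adjusted over the list alone; adjusted p = 0.0347, and adjusted p = 0.608 with an estimated correlation). Matrix remodelling genes rose in 7 of 20 and fell in 0 (7 and 1 adjusted over the list alone; adjusted p = 0.0134, and adjusted p = 0.608 with an estimated correlation), among them Mmp13 and Mmp10 (4.15). Of 16 glycolysis and hypoxia genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.000242, and adjusted p = 0.5 with an estimated correlation). Slc2a1 went from 74.1 ± 21.5 to 669 ± 272 FPKM (3.13, adjusted p = 0.00299), Vegfa rose by 2.21 and Pkm by 1.35. Basal keratinocyte genes rose in 3 of 13 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00833, and adjusted p = 0.5 with an estimated correlation): Krt14 rose by 3.07 (adjusted p = 0.00467) and Krt15 fell by 3.64 (adjusted p = 0.00211).

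Among 16 skeletal muscle genes 14 fell (16 adjusted over the list alone), 0 rose and 2 did not pass (adjusted p = 3.02e-13, and adjusted p = 0.255 with an estimated correlation). Myl1 went from 1491 ± 207 to 69.4 ± 71.4 FPKM (-4.92, adjusted p = 0.00156), Casq1 fell by 4.12 and Neb by 3.86. Adipocyte genes fell in 4 of 13 (12 adjusted over the list alone; adjusted p = 6.56e-06, and adjusted p = 0.5 with an estimated correlation), with Adipoq at -3.54 and Plin1 at -3.53. Melanocyte genes fell in 2 of 10 (9 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.5 with an estimated correlation), namely Mlana (-2.93) and Mitf (-1.71), while Dct did not pass (-3.32, adjusted p = 0.0556). Fibroblast genes fell in 3 of 9 (3 adjusted over the list alone; adjusted p = 0.00833, and adjusted p = 0.608 with an estimated correlation): Dcn (-3.05), Dpt and Lum (-2.15). Schwann cell genes fell in 4 of 6 and rose in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.00769, and adjusted p = 0.255 with an estimated correlation), with Mbp at -2.09; no Schwann gene rose when any 1 of the 5 libraries was left out. Fatty acid oxidation genes fell in 2 of 10 (2 adjusted over the list alone; adjusted p = 0.00633, and adjusted p = 0.255 with an estimated correlation), Cpt1b (-2.45) and Acadm (-1.36), and of 6 hedgehog pathway genes Ptch1 alone fell (-1.84; 5 adjusted over the list alone; adjusted p = 0.00324, and adjusted p = 0.5 with an estimated correlation). Krt77 (ENSMUSG00000067594, chromosome 15, 101858732 to 101869705) went from 952 ± 275 to 14.3 ± 3.67 FPKM (-5.94, SE 0.82, adjusted p = 0.00167), and Defb8, a defensin, was listed at 0 in all 6 tumours beside 92.2 ± 16 in WT skin.

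Cell cycle genes were higher throughout but passed seldom. All 28 mitosis genes were higher, and 0 passed over all genes or adjusted over the list alone (median 0.843, adjusted p = 5.75e-05, and adjusted p = 0.608 with an estimated correlation); the median was 0.391 without WT cSCC replicate 1 and 1.35 without WT cSCC replicate 2. All 24 DNA replication genes were higher and Ccne1 alone rose (1.79; 1 adjusted over the list alone; adjusted p = 0.000378, and adjusted p = 0.608 with an estimated correlation). Of the 6 followed-up genes 0 passed over all genes and 4 rose adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.5 with an estimated correlation); the study probably chose them on these samples, so neither count is independent evidence. Their log2 changes were 1.36 for Kif18b, 1.35 for Aurka, 1.03 for Cdk6, 0.96 for Orc1, 0.42 for Pkmyt1 and 0.39 for Fat2. Trp63 (0.08, adjusted p = 0.904), Trp53 (0.60, 0.278) and Trp73 (0.38, 0.681) did not pass.

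WT cSCC replicate 1 and replicate 2 differed in skin genes: the mean log2(FPKM + 1) of the hair list was 0.837 and 6.53. Without WT cSCC replicate 1, 464 genes were called; 5 wound, 4 glycolysis, 1 matrix and 1 basal gene rose, 6 muscle, 1 Schwann and 1 fatty acid oxidation gene fell, while 0 adipocyte, melanocyte, fibroblast, hedgehog and glycolysis genes fell and 0 DNA replication genes rose. Without WT cSCC replicate 2, 1907 were called; 11 chemokine, 7 basal, 6 mitosis, 3 followed-up, 2 DNA replication and 2 neutrophil genes rose, and 11 adipocyte, 6 melanocyte and 2 Schwann genes fell. Without WT skin replicates 1, 2 and 3, 994, 752 and 748 genes were called; matrix genes rose in 4, 3 and 3, glycolysis genes in 4 each and DNA replication genes in 0, 1 and 0. Adipocyte genes then fell in 1 each and melanocyte genes in 0, 0 and 1; without replicates 2 and 3, 1 fibroblast, 1 Schwann and 0 hedgehog genes fell, and without replicate 3, 1 fatty acid oxidation gene. With sex as a covariate, chosen after the data had been seen and informed by TAp63-/- cSCC replicate 1 alone, the number of genes changed, WT cSCC vs WT skin, was 255, with 7 wound, 0 muscle and 1 chemokine gene among them.

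TAp63-/- tumours were compared with TAp63-/- skin in the same way. Wound keratins and small proline-rich proteins rose again, together with inflammatory cytokines, matrix proteases and the glucose transporter gene Slc2a1. Interferon-induced antiviral genes (Oas1a, Rsad2, Ifi44) and drivers of the cell cycle (Cdk6, Ccne1, Aurka, Cdc20) rose. The median log2 change of mitosis genes was 0.801 here and 0.843 in WT tumours, and that of interferon genes 1.28 and 0.633. More tumours were compared here than in WT, so additional calls do not set the genotypes apart. Muscle, fat, sebaceous gland, melanocyte, fibroblast and nerve sheath genes fell, as did Flg2 and Lor, which build the cornified layer. Here too, the share of tissues and cell types in the piece was not separated from changes within cells.

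A total of 4017 genes were called, 1920 higher and 2097 lower, and 2460 of them changed at least 2-fold. Camera with an estimated correlation called 0 of the 33 lists here and fry called 15. Fry's adjusted p was lowest for Schwann cell genes (0.000183) and was 0.000295 for wound, chemokine and muscle genes. Krt6b averaged 2847 ± 1069 FPKM in the tumours (SD, n = 4) and 6.29 ± 3.94 in skin (n = 3; log2 change 8.74, SE 0.70, adjusted p = 2.07e-05). Krt16 averaged 1705 ± 520 and 11.5 ± 8.0 (7.29, SE 0.57, adjusted p = 1.86e-05). Stfa2 averaged 961 ± 229 and 2.36 ± 1.89 (8.37, adjusted p = 2.8e-05). Of 14 wound keratinocyte genes 11 rose (12 adjusted over the list alone), 0 fell and 3 did not pass (adjusted p = 1.29e-08, and adjusted p = 0.293 with an estimated correlation), Sprr1b by 8.89 and Sprr2d by 7.71. Of 19 chemokine and cytokine genes 13 rose (16 adjusted over the list alone), 0 fell and 6 did not pass (adjusted p = 3.84e-06, and adjusted p = 0.293 with an estimated correlation); Cxcl5 rose by 2.64 and Il1a by 2.32, and Il24 was listed at 0 in TAp63-/- skin. Matrix remodelling genes rose in 12 of 20 and fell in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.596 with an estimated correlation), among them Mmp13 (6.15) and Mmp10 (4.15). Glycolysis and hypoxia genes rose in 8 of 16 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.51 with an estimated correlation): Slc2a1 went from 54.5 ± 13.7 to 979 ± 390 FPKM (4.05, adjusted p = 6.28e-05), Vegfa rose by 2.18 and Aldoa fell by 2.05.

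Basal keratinocyte genes rose in 10 of 13 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00264, and adjusted p = 0.47 with an estimated correlation), with Itgb4, which anchors basal cells to the basement membrane, at 2.02 and Krt15 at -4.46. Trp63 rose by 0.90 (SE 0.29, adjusted p = 0.0377), a call lost in 10 alternatives, among them sex as a covariate and the fit on these 7 libraries only. Its relatives Trp53 (0.36, adjusted p = 0.374) and Trp73 (1.22, adjusted p = 0.0569) did not pass. Cornified differentiation genes fell in 8 of 22 and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.644 with an estimated correlation), Flg2 by 4.80 and Lor by 2.58. Krt77 fell by 8.12 (SE 0.69, adjusted p = 2.48e-05), and Defb8 was listed at 0 in the tumours beside 570 ± 494 FPKM in TAp63-/- skin.

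Neutrophil genes rose in 4 of 9 and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0223, and adjusted p = 0.596 with an estimated correlation): Cxcr2 and Clec4e each rose by 2.49 and Il1r2, a decoy receptor, fell by 1.52. Interferon response genes rose in 4 of 18 and fell in 0 (4 adjusted over the list alone; adjusted p = 0.00503, and adjusted p = 0.637 with an estimated correlation), with Ifi44 at 1.81, Oas1a at 1.76 and Rsad2 at 1.12. Mitosis genes rose in 8 of 28 and fell in 0 (8 adjusted over the list alone; adjusted p = 0.000463, and adjusted p = 0.637 with an estimated correlation), such as Cdc20 (1.37) and Cenpa (1.31). DNA replication genes rose in 5 of 24 and fell in 0 (3 adjusted over the list alone; adjusted p = 0.000911, and adjusted p = 0.637 with an estimated correlation), with Ccne1 at 2.33 and Gins1 at 1.06. Of the 6 followed-up genes, 5 rose over all genes and 6 adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.392 with an estimated correlation), which is not independent evidence where the study chose them on these samples. These were Cdk6 (1.58, SE 0.27, adjusted p = 0.00165), Kif18b (1.42), Orc1 (1.40), Fat2 (1.38) and Aurka (1.36, SE 0.35, adjusted p = 0.0156), while Pkmyt1 did not pass over all genes (0.63, adjusted p = 0.066).

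All 16 skeletal muscle genes fell (16 adjusted over the list alone; adjusted p = 1.69e-14, and adjusted p = 0.293 with an estimated correlation), Myl1 by 5.99, Casq1 by 5.21 and Neb by 4.98. Sebaceous gland genes fell in 9 of 10 (10 adjusted over the list alone; adjusted p = 3.84e-06, and adjusted p = 0.293 with an estimated correlation), among them the wax synthase gene Awat2 (-3.09), Cidea (-2.43) and Mgst1 (-1.51). Adipocyte genes fell in 11 of 13 (12 adjusted over the list alone; adjusted p = 9.84e-07, and adjusted p = 0.47 with an estimated correlation), with Adipoq at -4.44. Melanocyte genes fell in 6 of 10 (9 adjusted over the list alone; adjusted p = 0.000374, and adjusted p = 0.51 with an estimated correlation), with Dct at -3.60. Fibroblast genes fell in 6 of 9 (6 adjusted over the list alone; adjusted p = 0.000654, and adjusted p = 0.47 with an estimated correlation), with Dcn at -4.19 and Lum at -2.84. Schwann cell genes fell in 5 of 6 (5 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.293 with an estimated correlation), with Mbp at -2.11. Hedgehog pathway genes fell in 2 of 6 (2 adjusted over the list alone; adjusted p = 0.0398, and adjusted p = 0.596 with an estimated correlation), Shh (-2.04) and Ptch1 (-1.45).

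Without TAp63-/- skin replicate 1, 2432 genes were called; 6 basal, 3 followed-up, 2 DNA replication, 1 mitosis, 1 neutrophil, 1 interferon and 0 cornified genes rose, and 4 cornified and 0 neutrophil genes fell. Without TAp63-/- skin replicate 2, 3 followed-up, 3 mitosis, 2 DNA replication, 2 neutrophil, 1 interferon and 1 cornified gene rose, and 4 cornified, 1 hedgehog and 0 neutrophil genes fell; without replicate 3, 1 interferon gene rose, and 3 melanocyte and 1 hedgehog gene fell. Without TAp63-/- cSCC replicate 3, 11 interferon, 5 mitosis and 2 DNA replication genes rose, and without replicate 4 it was 1, 3 and 3, with 4 hedgehog genes that fell. Without TAp63-/- cSCC replicate 1, 1 interferon gene rose, and without replicate 2, 3 DNA replication genes and 1 Schwann gene rose and 5 cornified genes fell; 1 hedgehog gene fell without each of replicates 1, 2 and 3. With sex as a covariate the number of genes changed, TAp63-/- cSCC vs TAp63-/- skin, was 1939.

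The tumour-skin comparisons of the genotypes set different libraries against each other, but both were fitted on all 12 and share each gene's variance estimate, so the numbers expected from independent calls are a reference and not a test. Of the genes that rose in WT tumours 593 (86.2%) also rose in TAp63-/- tumours, where 89.5 were expected if the calls were independent, and of those that fell 920 (92.1%) also fell, where 142 were expected. Without WT cSCC replicate 1 the shared calls were 189 and 233, against 30.9 and 36 expected; without WT skin replicates 1, 2 and 3 they were 316 and 615, 246 and 463, and 239 and 468. Without TAp63-/- skin replicates 1 and 2 they were 427 and 872, and 392 and 742. A total of 5 genes were called in opposite directions, Skint3, Skint4, Skint9, Cyp2j8 and 2810403D21Rik. Skint9 rose by 2.23 in WT tumours against WT skin and fell by 5.18 in TAp63-/- tumours against TAp63-/- skin, Skint3 rose by 3.54 and fell by 2.29, and Skint4 rose by 1.84 and fell by 2.77. Cyp2j8 and 2810403D21Rik, named after their values were seen, did not pass the test of the difference itself (adjusted p = 0.426 and 0.0936).

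**Figure D3:**
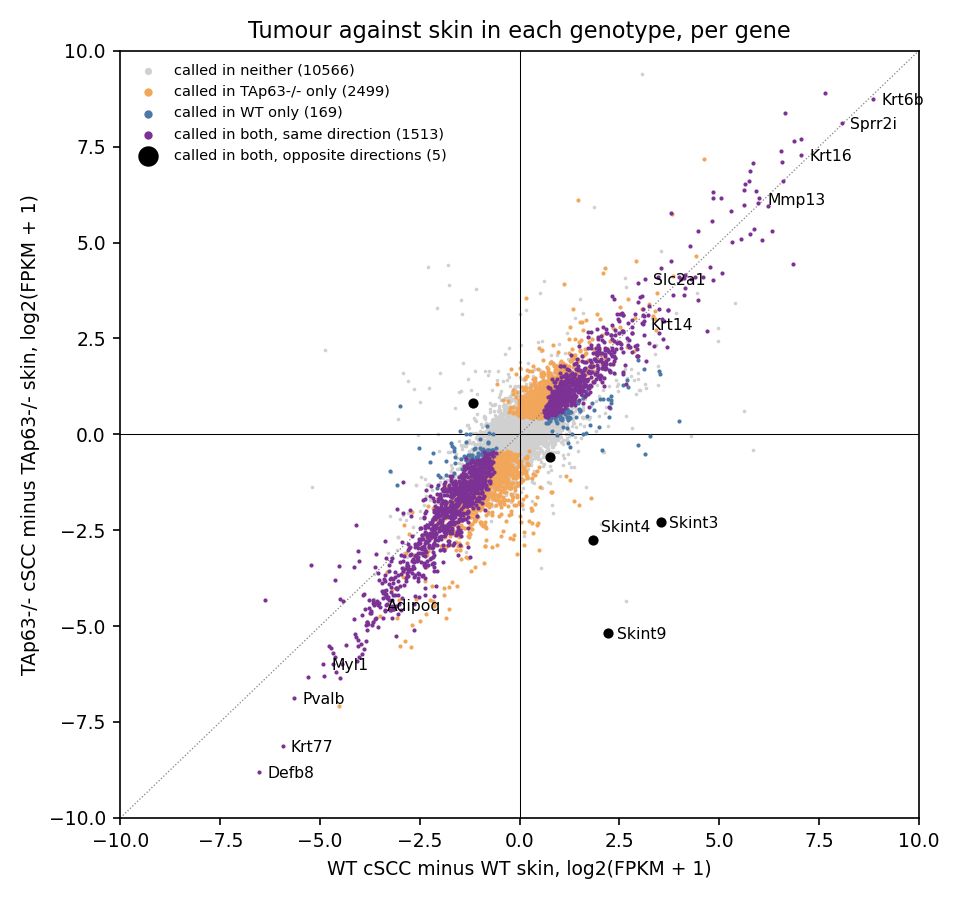
Log2 change of each tested gene, WT cSCC minus WT skin (x axis) against TAp63-/- cSCC minus TAp63-/- skin (y axis), coloured by the comparison in which it was called. Pearson's r across genes was 0.862, and the 5 genes called in opposite directions include Skint3, Skint4 and Skint9.

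The comparison of TAp63-/- with WT tumours asked what the loss of TAp63 changed in established tumours. No gene passed. Zfp618, a zinc finger protein gene, and Gpx2, which encodes a glutathione peroxidase that removes peroxides, had among the smallest p-values and were lower.

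Limma called 0 of 14752 genes (419 at an unadjusted p below 0.05, smallest adjusted p = 0.126), camera with an estimated correlation called 0 lists and fry called 0. Zfp618 (ENSMUSG00000028358, chromosome 4, 62965573 to 63139708) had 19.0 and 11.3 FPKM in the WT tumours and 0.280, 0.242, 0.576 and 0.153 in the TAp63-/- tumours (log2 change -3.59, SE 0.30, adjusted p = 0.126). Gpx2 (ENSMUSG00000042808, chromosome 12, 76792335 to 76795554) had 293 and 66.8 FPKM in WT and 7.03, 4.76, 1.04 and 8.42 in TAp63-/- tumours (-4.69, SE 0.79, adjusted p = 1). Its pseudogene Gpx2-ps1 differed by -3.87. Whether those values come from reads shared with Gpx2 was not tested, so it is not a separate observation. Stac differed by -1.88. The genes with the smallest p that were higher were AL606528.1 (3.48), Cd180 (1.45), Mtss1 (1.38) and Zfp771 (1.16). None of these genes passed. The followed-up genes differed by 0.79 (Fat2), 0.56 (Cdk6), 0.10 (Orc1), -0.17 (Pkmyt1), -0.44 (Aurka) and -0.48 (Kif18b), none passing. The count was 11 without WT cSCC replicate 1, 5 without WT cSCC replicate 2, 1 without TAp63-/- cSCC replicate 2, 9 with no filter on low values and 1 in the fit on all 12 libraries (Zfp618, adjusted p = 0.00121).

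Camera at the preset correlation placed 8 lists lower and 2 higher in TAp63-/- tumours, with no member passing over all genes. Sebaceous gland genes were lower by a median of -1.34 (adjusted p = 3.35e-09, and adjusted p = 0.765 with an estimated correlation), 4 of 10 fell adjusted over the list alone, and the median was -1.98 without WT cSCC replicate 1 and -0.76 without replicate 2. Fa2h (-2.57), Elovl3 (-2.55) and Cidea (-1.45), which make or store sebum lipids, had the smallest p of that list. In the other 9 lists 0 members passed when adjusted over the list alone. Schwann cell genes were lower by a median of -0.298 (adjusted p = 0.00865, and adjusted p = 0.765 with an estimated correlation), and -0.468 without TAp63-/- cSCC replicate 1. Lists of adipocyte (-1.22), muscle (-1.13), hair (-1.40), melanocyte (-0.546), cornified (-0.623) and mitosis genes (-0.254) were lower at adjusted p = 2.18e-06, 2.26e-05, 0.000371, 0.00074, 0.00222 and 0.00316, each at adjusted p = 0.869 with an estimated correlation. Without WT cSCC replicate 2 these medians were -0.186, -0.145, 1.61, 0.137, 0.108 and -0.745, and without replicate 1 -2.37, -2.24, -4.58, -1.19, -1.42 and 0.187. Interferon response genes were higher in 18 of 18 (median 0.674, adjusted p = 0.00222, and adjusted p = 0.869 with an estimated correlation), but the median was -0.249 without WT cSCC replicate 1 and 1.62 without replicate 2. Matrix remodelling genes were higher in 17 of 20 (median 0.347, adjusted p = 0.0455, and adjusted p = 0.869 with an estimated correlation), with medians of 0.605 and 0.118 without replicates 1 and 2. For genes changed, TAp63-/- cSCC vs WT cSCC, leaving out TAp63-/- cSCC replicate 1 gave medians of -0.148 (mitosis), 0.628 (matrix) and -0.961 (cornified), replicate 2 gave 0.23 (matrix), replicate 3 gave 1.14 (interferon), -0.189 (cornified) and -0.794 (hair), and replicate 4 gave -0.401 (mitosis) and 0.185 (matrix).

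The interaction asked whether the change from skin to tumour differed between the genotypes. Skint3, Skint4 and Skint9 and the zinc finger gene Zfp618 changed less or in the other direction in TAp63-/- tissue. For the Skint genes this mostly restates the genotype difference in skin (6.19 for Skint9, 5.46 for Skint3 and 4.30 for Skint4). Between TAp63-/- and WT tumours they differed by -1.21, -0.36 and -0.31 in that order, none passing.

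With limma, 4 of 14752 genes were called, all lower, and 444 had an unadjusted p below 0.05; in simulated data for the interaction 14 of 79 calls were false. The difference of log2 changes was -7.40 for Skint9 (SE 0.39, adjusted p = 1.47e-05), -5.83 for Skint3 (SE 0.64, adjusted p = 0.0119), -4.61 for Skint4 (SE 0.52, adjusted p = 0.0119) and -3.31 for Zfp618 (SE 0.40, adjusted p = 0.0163). Zfp618 rose by 3.27 from WT skin to WT tumours (adjusted p = 0.000271) and did not change in TAp63-/- tissue (-0.04, adjusted p = 0.926). The call of Zfp618 was lost in 8 alternatives and those of Skint3 and Skint4 without WT cSCC replicate 2, WT skin replicate 2 or TAp63-/- skin replicate 2. Skint4, genotype by tissue interaction, was also lost among genes with a mean of at least 5 FPKM (adjusted p = 0.0581). The count was 15 without WT cSCC replicate 1, and 1 each without WT skin replicate 2 and TAp63-/- skin replicate 2. Trp63 differed by 0.82 (SE 0.45, adjusted p = 1).

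Camera called 6 lists in the interaction, none with an estimated correlation, and fry called 0 (lowest adjusted p = 0.559). Sebaceous gland genes differed by a median of -1.64 (adjusted p = 1.31e-10, and adjusted p = 0.353 with an estimated correlation), 5 of 10 fell adjusted over the list alone and 0 over all genes, with Elovl3 at -3.09, Fa2h at -2.92 and Cidea at -1.59. In the other 5 lists 0 members passed, over all genes or adjusted over the list alone. Muscle (-1.21), cornified (-1.04) and fibroblast genes (-0.649) were lower and immediate-early (0.846) and interferon genes (0.59) higher, at adjusted p = 4.94e-06, 7.75e-06, 0.0419, 0.00239 and 0.0419, and at adjusted p = 0.999 with an estimated correlation. Of these lists for genes changed, genotype by tissue interaction, the muscle, cornified, immediate-early and interferon medians were -2.44, -1.82, 0.336 and -0.302 without WT cSCC replicate 1 and -0.168, -0.465, 1.36 and 1.51 without replicate 2. The sebaceous median was -0.961 without WT cSCC replicate 2, and 1 sebaceous gene passed over all genes without replicate 1. The fibroblast median was -0.432 without TAp63-/- cSCC replicate 1 and -0.989 without replicate 2, and the interferon median 0.34 without replicate 2 and 0.926 without replicate 3.

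**Figure D4:**
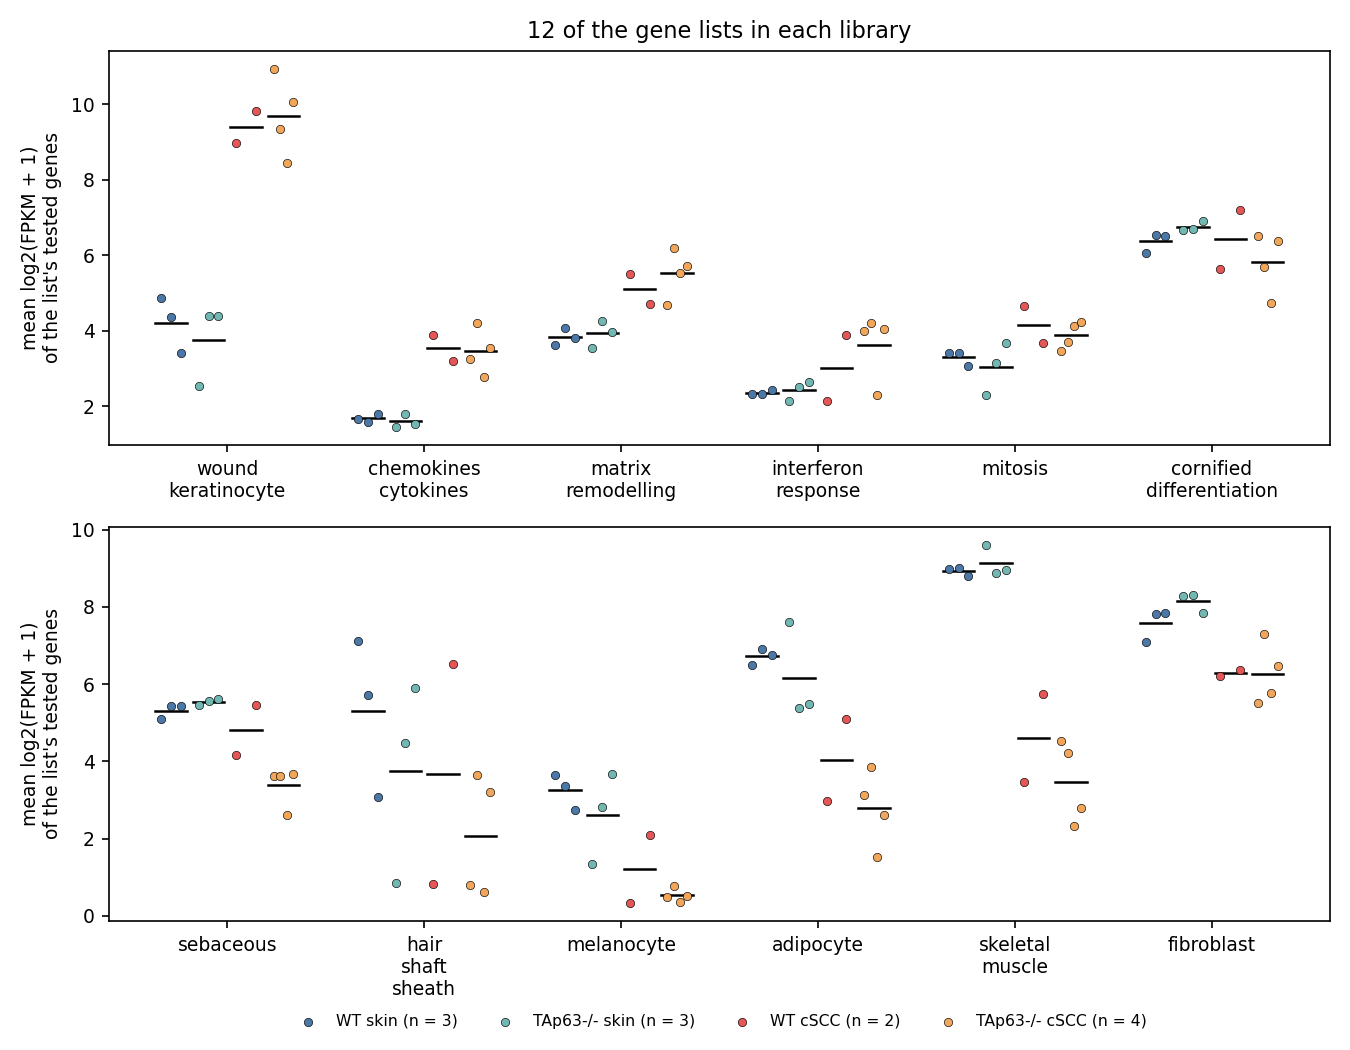
Mean log2(FPKM + 1) of the tested genes of 12 lists in each library (points) with group means (bars), in 2 panels. The hair list was 0.837 and 6.53 in the WT tumours and ran from 0.856 to 7.11 in the skin libraries.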

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

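The counts over other splits of the samples were set before the result was seen; the tests on the Skint genes, WT cSCC replicate 2 and the hair genes were chosen after it.

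A difference between the genotypes in the change from skin to tumour passed for Skint9 (-7.40), Skint3 (-5.83), Skint4 (-4.61) and Zfp618 (-3.31). Skint3, Skint4 and Skint9 were near 0 in WT skin, at 0.0369 FPKM or less. Failed estimates are argued against, since 7 of the 9 values were above 0 and all 9 were low. Loss of TAp63 alone stays open: the lowest WT tumour values were 408, 116 and 92.6 times the highest WT skin value of Skint3, Skint4 and Skint9, but tumours differ from skin in tissue, age, ultraviolet exposure and sex, and TAp63 itself was not measured. Reads shared among Skint paralogs stay open as well: the members that were lower in TAp63-/- skin lost 0.222 of what the others gained, with 0.0657 to 1 over single pairs of libraries. A different chromosome segment in the WT skin mice, such as a lost or divergent stretch across these neighbours, may also explain the pattern and stays open: of the 100 other genes with the smallest p, 23 pairs lay within 2 Mb (median of 10000 random draws 15, permutation p = 0.058), and another split of the libraries gave 42.

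Of the 6 lists that differed between the genotypes in camera's interaction test, sebaceous genes had a median of -1.64, muscle -1.21, cornified -1.04 and fibroblast genes -0.649, while immediate-early genes had 0.846 and interferon genes 0.59. None of these held with an estimated correlation, and the interferon median changed sign without WT cSCC replicate 1.

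In WT cSCC replicate 2 skin and appendage genes were high: the hair list stood at a median of 1.32 times the WT skin level, against 0.00155 in replicate 1. Full-thickness skin in the sampled piece stays open. The fractions of 5 lists differed 12.7 times (11, 14.2 and 101 against each WT skin library), with muscle at 0.104 and adipocyte genes at 0.304. Each of these ratios was above the limit set beforehand for arguing against this explanation, a limit that takes skin to carry its parts in equal shares. Skin libraries did not carry all parts alike either. Over them the mean log2(FPKM + 1) of the hair list ran from 0.856 to 7.11 and that of the muscle list from 8.81 to 9.61. Unequal fractions therefore cannot decide the question. Hair follicle material in the sampled piece may account for the hair genes, at 1.32. Melanocyte genes at 0.296 were above replicate 1 (0.0082), as this explanation predicted. It stays open, since the muscle fraction of 0.104 did not stay under the limit set for it. Sebaceous genes at 0.983 were also above replicate 1 (0.383). The labels give no group that separates both tumours, so no biological explanation was tested.

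Hair genes differed between the skin libraries: the list's mean log2(FPKM + 1) was 7.11, 5.72 and 3.07 in WT and 0.856, 4.48 and 5.91 in TAp63-/- skin. More or less epidermis in the piece stays open: basal and cornified lists ran the other way, but neither relation passed (Pearson's r = -0.726, permutation p = 0.103, adjusted 0.206, rho = -0.714, permutation p = 0.136, adjusted 0.363; r = -0.352, permutation p = 0.504, adjusted 0.504, rho = -0.143, permutation p = 0.803, adjusted 0.918). Hair cycle stage is a candidate explanation and stays open too, as hedgehog genes gave the lowest r, 0.776 (permutation p = 0.0778, adjusted 0.206, rho = 0.543, permutation p = 0.297, adjusted 0.57). Mitosis genes gave r = 0.913 (permutation p = 0.00972, adjusted 0.0389, rho = 0.83, permutation p = 0.0583, adjusted 0.233) and melanocyte genes r = 0.961 (permutation p = 0.00278, adjusted 0.0222, rho = 0.943, permutation p = 0.0167, adjusted 0.134), among 8 relations over 6 libraries; no rank relation passed after adjustment. Without TAp63-/- skin replicate 1 and WT skin replicate 3 the r of hedgehog, mitosis, melanocyte, basal and cornified genes was 0.144, 0.522, 0.884, 0.229 and -0.687, so the hedgehog, mitosis and basal values rest on those libraries. Within TAp63-/- skin the cornified and hedgehog r were positive and within WT skin both were negative, over too few libraries to test.

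Of the 35 splits of the 7 TAp63-/- libraries into 4 and 3, only the real split itself called 4017 genes (highest other 1744). That share, 1 in 35, is under 0.05 and argues against chance. It is also the lowest share these splits can give, so chance is not excluded. The 10 splits of the 6 skin libraries, of which 1 reached the real count, are too few for a share under 0.05 (3 genes called, highest other 1).

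Among the 4 TAp63-/- tumours, 19 of 133 named genes and 4 of 33 lists had 1 library far from the others; chance gives about 1 in 20 for normally distributed values, which FPKM need not be. In replicate 1 the Y-linked Eif2s3y was 60.1 FPKM (0 to 0.0197 in the others), the only male tumour by expression. Replicate 1 also had Mb at 55.3 (4.15 to 10.6), Cpt1b at 3.01 (0.739 to 1.06) and Chaf1a at 4.46 (5.91 to 6.18), with DNA replication genes at a mean log2 value of 3.36 (3.93 to 3.98). In replicate 2 Spp1 was 886 FPKM (27.1 to 46.2), Postn 466 (376 to 384), Slc2a1 401 (1101 to 1245), Lpl 84.1 (5.07 to 17.8), Dpt 56.3 (14.7 to 19.1), Clec4e 25.3 (2.55 to 4.42), Myh4 23.1 (0.218 to 2.07) and Oca2 0.0185 (0 in the others), and the epithelial-mesenchymal transition list was 4.64 (3.75 to 3.86). In replicate 3 Padi3 was 83.8 FPKM (0.282 to 4.5), Mgst1 32.1 (50.5 to 53.8), Ifit3 2.06 (6.29 to 6.89) and Flg2 0.531 (2.04 to 2.31), the interferon list was 2.29 (4.01 to 4.2) and the sebaceous list 2.61 (3.61 to 3.67). In replicate 4 Fos was 115 FPKM (33 to 39.5), Nusap1 35.2 (10.1 to 14) and Shh 3.04 (0 to 0.179).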

How the results depend on the processing

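Sex and hair covariates were added after the data had been seen. Of the counts under alternatives 85 stayed within 1.5 times and 23 moved; of the named genes' values 4562 kept direction and side of the threshold, 33 came to pass, 199 no longer passed and 39 reversed.

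For genes changed, TAp63-/- skin vs WT skin, a pseudocount of 0.1 gave 5. For genes changed, WT cSCC vs WT skin, sex as covariate gave 255. For genes changed, TAp63-/- cSCC vs TAp63-/- skin, at least 2-fold as well gave 2460 by construction and sex as covariate 1939. For genes changed, TAp63-/- cSCC vs WT cSCC, no filter on low values gave 9 and all 12 libraries in the fit 1. For genes changed, genotype by tissue interaction, a mean value of at least 5 gave 2: Zfp618 was not tested and Skint4 no longer passed. Lists called went from 59 to 0 with camera with estimated correlation and 22 with fry. All of fry's calls lay in the tumour-skin comparisons, 7 in WT and 15 in TAp63-/- tissue. The cause of the other moves was not tested.

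With 1 library left out, the counts ran from 3 to 8 in skin, 464 to 1907 for WT tumours against skin, 2432 to 4446 for TAp63-/- tumours against skin, 0 to 11 between tumours and 1 to 15 for the interaction. For these ranges only libraries of the compared groups were left out. The tumour-skin fits take their spread from all groups, so other libraries matter too. For WT tumours against skin, the count was 2115 without TAp63-/- cSCC replicate 2 and 1952 without TAp63-/- cSCC replicate 3. A lone remaining WT tumour is assumed to vary like the other groups.

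None of the genes that reversed was called, and the cause was not tested. In skin, Cdk6 was -0.0074 with median-of-ratios scaling and -0.070 with the hair list as covariate, which gave 0.013 for Trp53. Trp63 in WT tumours against skin was -0.047 with the hair list. Between tumours, Orc1 was -0.28 with the skeletal muscle list and -0.13 with the hair list as covariate. In the interaction a pseudocount of 5 gave -0.12 for Kif18b and -0.098 for Aurka, median-of-ratios -0.028 for Aurka, and array weights 0.073 for Trp53.

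With 1 library left out, Cdk6 ran from -0.12 to 0.15 and Trp53 from -0.31 to 0.0059 in skin, and Trp63 from -0.18 to 0.35 and Trp73 from -0.52 to 1.27 in WT tumours against skin. Between tumours the ranges were Orc1 -0.41 to 0.61, Pkmyt1 -0.49 to 0.15, Ccnb1 -0.96 to 0.069, Kif18b -1.20 to 0.25, Plk1 -1.39 to 0.15, Trp73 -0.25 to 1.54, Msx2 -1.88 to 0.026, Hoxc13 -2.71 to 0.41 and Tyrp1 -3.41 to 0.019. In the interaction they were Kif18b -0.66 to 0.78, Aurka -0.43 to 0.44, Trp53 -0.58 to 0.10, Trp73 -0.056 to 1.74, Orc1 -0.072 to 0.94 and Pkmyt1 -0.10 to 0.53.

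Of 47 named genes called in WT tumours against skin, sex as covariate lost 37, leaving out WT cSCC replicate 1 lost 22 and WT cSCC replicate 2 lost 4. Of 66 in TAp63-/- tumours against skin, sex lost 23 and leaving out TAp63-/- skin replicate 1 lost 9. No paired analysis was possible because replicate numbers follow the order of deposition. A count-based test was not run, and another choice of libraries does not apply to the interaction. Read depth is unknown, so what it limits could not be stated.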

Other observations

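The tests in this part were planned, except that Mir17hg, Mir497 and Mir30c-2 were chosen after the values were seen. Mir17hg, the host gene of the miR-17~92 cluster, had 3.37 and 3.99 FPKM in the WT tumours, 4.36, 5.82, 4.91 and 5.16 in the TAp63-/- tumours, 0.5, 0.453 and 0.304 in WT skin and 0.285, 0.277 and 0.22 in TAp63-/- skin. Mir17hg rose in WT tumours against WT skin (1.72, SE 0.19, adjusted p = 0.000561) and in TAp63-/- tumours against TAp63-/- skin (2.26, SE 0.16, adjusted p = 9.55e-06). Mir497 and Mir30c-2 were listed at 0 in all 12 libraries, which does not show absence. Both entries are short (chromosome 11, 70234717 to 70234800, and chromosome 1, 23291701 to 23291784). Whether these libraries retain RNAs of that length was not tested, so the 0 values say nothing about their level.

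Several fixed lists did not pass camera in either tumour-skin comparison. Of 14 p53 target genes, 1 rose and 2 fell in each; in WT tumours 0 fell without WT cSCC replicate 1, 4 without WT cSCC replicate 2, and 1 each without WT skin replicates 1 and 3. Of 10 microRNA processing genes, 0 rose and 1 fell in WT and 2 rose and 1 fell in TAp63-/- tumours, and of 5 genes reported as TAp63 targets 1 and 2 fell. In WT tumours the reported target no longer passed when any 1 of the 5 libraries was left out, and the microRNA processing gene that fell no longer passed without WT cSCC replicate 1 or WT skin replicates 2 or 3. In TAp63-/- tumours 1 reported target fell without TAp63-/- cSCC replicates 3 or 4 or without any 1 skin library. With any 1 of these 5 libraries left out 1 microRNA processing gene rose, and 0 fell without TAp63-/- cSCC replicate 4 or skin replicates 1 or 2. Hair genes changed in 0 of 19 in each (median -1.54 and -1.61, camera adjusted p = 0.109 and 0.0765). The WT median was 1.11 without WT cSCC replicate 1 and -4.19 without replicate 2, and the TAp63-/- median ran from -2.45 without TAp63-/- skin replicate 1 to -0.286 without TAp63-/- skin replicate 3.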
